A study of Mus musculus with 10 samples.

How the data were processed

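DNase I hypersensitivity was measured by sequencing the small DNA fragments that DNase I releases from liver nuclei of ICR mice at 8 weeks of age. The 10 libraries comprised male liver (n = 2), female liver (n = 2), liver of males given rat growth hormone (GH) without interruption from an osmotic pump at 20 ng per hour and gram of body weight for 7 days (n = 2), and 4 naked DNA controls, 1 sonicated and 1 DNase-digested for each sex. Per the labels' protocols, each biological replicate was a pool of nuclei, its DNA came from at least 3 digestions, and fractions were chosen before sequencing by quantitative PCR for strong enrichment and for strong differences between the sexes. That selection favours the known sex differences and applies to every comparison.

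Per the labels' protocols the authors aligned the reads to mouse genome mm9 with Eland extended, and the deposited read files give 1 line per mapped read with no further scaling. The deposited peak lists hold, per the deposited text on their columns, the read count of each of the 2 samples compared in the region. They also hold the ratio of these counts (a fold) and the p-value of the authors' comparison. In regions listed as higher in male than GH-treated liver, the summed counts were 0.926 (male) and 1.21 (GH-treated) times the reads counted here. In the reverse list they were 0.776 (GH-treated) and 0.572 (male) times. Whether counts and fold are scaled by library size is therefore not settled here. The peak caller and its version are not given in the sources used here. Lists against naked DNA exist for each male and female replicate and for the pooled reads of each group, and 4 further lists compare male with female and male with GH-treated liver directly, 1 in each direction. No per-sample column was left unused (0).

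Sites were the merged union, joined at an overlap of 1 bp, of the pooled peak lists of the 3 groups against naked DNA, on the autosomes and X. Each read was counted once, at its 5-prime end. Reads of Y, the mitochondrial genome and unplaced sequences were left out of the sites. Each site was given to the gene with the nearest transcription start within 100 kb, from 72036 starts of 23623 genes in the GENCODE vM1 annotation on NCBIM37 (mm9). A gene name beside a site therefore means the nearest start, not a measured target. Promoter sites lie within 1 kb of a start. Overlaps of regions were computed in Python.

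All 6 liver libraries entered 1 fit in edgeR 4.0.16 (R 4.3.3): TMM scaling over the sites, the filterByExpr filter by group, trended dispersion, and quasi-likelihood tests of female minus male, GH-treated minus male and GH-treated minus female, two-sided. P-values were adjusted by the Benjamini-Hochberg method over all tested sites, with a threshold of 0.05. Fold changes are given as log2 ± standard error (SE), where the SE is the size of the log2 change divided by the square root of the F statistic. Site levels are CPM, reads scaled by TMM library size, as mean ± standard deviation (SD). DESeq2 1.42.0 served as a second test. Counts were simulated for female minus male over 55883 sites, with 200 sites changed in each of 5 simulations. With counts drawn at the trended dispersion this fit recovered 15% of 2-fold and 65% of 4-fold changes, and 5.44% of its calls were false. With counts drawn at a dispersion of each site's own (tagwise), the same fit recovered 10.4% and 60.8%, and 21.9% of its calls were false. In the unchanged GH-treated minus male comparison it made 0 calls at the trended and 28 at the tagwise dispersion.

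A total of 18 gene lists was fixed before the data were examined: male-biased and female-biased liver genes, GH and STAT5 signalling, liver transcription factors, hepatocyte genes, xenobiotic metabolism, lipid and sterol metabolism, the circadian clock, acute phase and inflammation, markers of Kupffer cells, sinusoidal endothelium, stellate cells, cholangiocytes, lymphocytes and erythroid cells, housekeeping genes, genes silent in liver, and X inactivation. Each was tested over its sites with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists. The list median, mean and test differ in sign for lymphocytes in female minus male (median 0.16, mean −0.31, lower), for lipid and sterol metabolism (0.06, −0.02, higher) and liver transcription factors (0.01, −0.02, higher) in GH-treated minus male, and for male-biased genes (0.20, −0.20, higher) and stellate cells (0.11, −0.02, higher) in GH-treated minus female liver.

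Sites are named by a rule fixed before the data were examined. It takes, per comparison and direction, the first 10 called sites in order of p in which the libraries of the 2 groups do not overlap, at least 50 kb apart, then the site with the lowest p for up to 6 genes of each of the male-biased, female-biased and GH signalling lists, and the 3 windows of 1 Mb with the most called sites. Other list members, genes with many called sites and single X sites were named after their values were seen. Some sites that the rule or a list would name are not reported here, and the counts include them.

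The read files fall into 2 processing batches by content. Male 1, female 1 and both sonicated controls hold reads on Y and unplaced sequences, and the other 6 libraries hold none. The GH-treated libraries are all in the second batch. Values with the batch as a block and from the second batch alone therefore stand beside the main ones. Both GH-treated libraries also differ from every male and female liver library in the labelled variation of fragment size (coefficient 54.4% and 40.7% against 100%). Their read files hold 1 block each and those of male and female liver 2. Neither setting separates these differences from the treatment, in any comparison with GH-treated liver. Replicate numbers were not used as pairs: after removal of group means, replicate deviations correlated across sites at 0.487 between male and female, −0.0123 between male and GH-treated, and 0.00254 between female and GH-treated liver. The second of 2 blocks in the female 2 read file holds no reads on 9:77430884–96953972 and X:91810908–98575388, where 2 unreadable lines stand and were left out. The stretches hold 361 of 55883 tested sites (0.646%), no site named in the fixed rule, and 13 of the sites called lower in female and 1 called lower after GH.

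Sex-biased autosomal sites outside these stretches were searched for 6 consensus motifs against unchanged sites matched for width, GC content and read level, and sequence matches to Y were found with BLAST+ 2.17.0. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for counting and plots. Alternatives covered other scalings, tests, filters, site definitions, duplicate removal, blocks, subsets of libraries and single libraries left out. Intervals on shares of reads and of sites are exact 95% Clopper-Pearson intervals and cover counting error only. Fisher's exact tests take sites as independent, although called sites cluster by locus, so they overstate the precision.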

Results

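Open chromatin was mapped in mouse liver to ask where it differs between the sexes and how far continuous GH, which gives a male the unbroken hormone exposure of a female, moves male liver toward the female state. Liver nuclei of 3 groups were digested with DNase I, a nuclease that cuts accessible DNA: males (n = 2), females (n = 2) and GH-treated males (n = 2). Male libraries held 13054393 and 16163854 mapped reads, female libraries 13047602 and 13357731, and GH-treated libraries 11290606 and 11677747. The naked DNA controls held 4768664 (sonicated, male), 4996227 (sonicated, female), 7257881 (DNase-digested, male) and 6894249 (DNase-digested, female) reads. Each of these controls was a single library.

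Reads from liver nuclei concentrated in 146459 sites that covered 1.82% of the autosomes and X, with a median width of 167 bp. Male libraries had 34.8% ± 8.33 (SD, n = 2) of their reads in the sites, female libraries 37.9% ± 6.27 (SD, n = 2) and GH-treated libraries 31.8% ± 2.16 (SD, n = 2). In naked DNA the same sites held 3.01% of the reads (exact interval 2.99 to 3.02) in sonicated male DNA, 2.85% (2.84 to 2.87) in sonicated female DNA, 3.75% (3.73 to 3.76) in digested male DNA and 4.08% (4.06 to 4.09) in digested female DNA. Liver groups thus exceeded the mean of the controls 10.2-fold (male), 11.1-fold (female) and 9.31-fold (GH-treated). An excess was fixed in advance, as the sites are peaks called in these libraries against these controls. Introns held 41.2% of the sites, intergenic sequence 34.2%, promoters 18.2%, coding exons 3.76% and untranslated regions 2.09%. Within each processing batch the female library had the larger share of reads in sites: 33.5% against 28.9% in the first batch, and 42.3% against 40.7% in the second, where the GH-treated libraries had 30.3% and 33.3%. The differences between group means were smaller than the spread between the 2 male replicates, which are in different batches. Within the second batch both GH-treated libraries lay below male 2 and female 2.

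**Figure D1:**
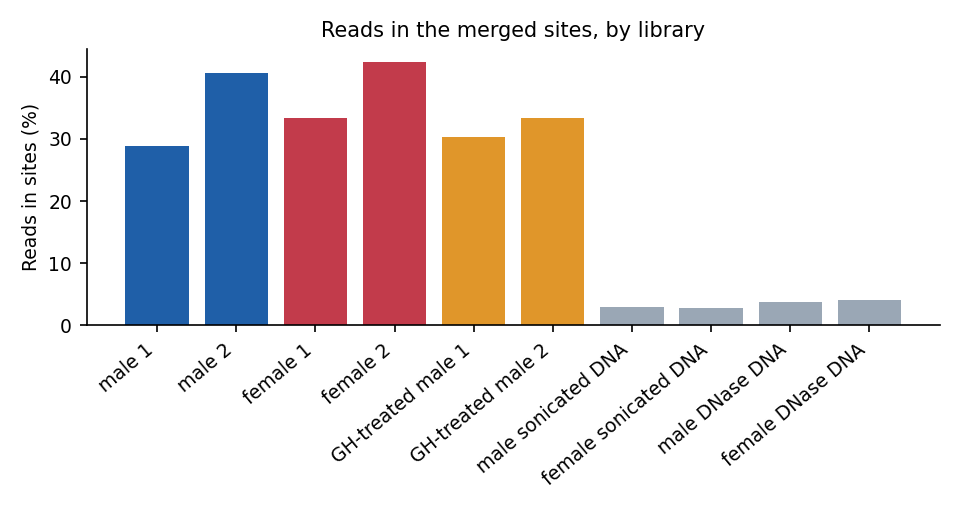
Percent of mapped reads that fall in the sites, for each of the 10 libraries. The 6 libraries of liver nuclei lie between 28.9% and 42.3%, and the 4 naked DNA controls between 2.85% and 4.08%.

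Peaks of the shorter of 2 deposited lists were largely shared with the longer one. Of the shorter list, 85.5% of peaks overlapped the other replicate in male liver and 81.7% in female liver. Of the longer list, 51.2% (male 2) and 63.2% (female 2) did. Between pooled lists the shared part of the shorter list was 74.9% for male and female, 70.7% for GH-treated and male, and 67.9% for GH-treated and female. Across sites, which are not independent replicates, Pearson's correlation of log2 CPM was 0.919 between male replicates, 0.928 between female replicates and 0.95 between GH-treated replicates, and 0.869 to 0.938 between libraries of different groups. Male and female replicates are in different batches and GH-treated ones in the same batch, so these 3 values are not alike. Libraries of different groups within the second batch correlated at 0.915 to 0.938, about as well as male or female replicates. In the first batch male 1 and female 1 correlated at 0.901. A site was in all 3 pooled lists in 55626 cases and in 1 list in 68655. Of all sites, 55883 had enough reads to be tested.

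Female and male liver differed at sites such as those of Cux2, Ttc39c, Scara5 and Rhd, and at a pair of X-linked loci. An intronic site of Cux2, a homeobox transcription factor, was 13.9-fold higher in female liver (log2 3.79 ± 0.31 SE, n = 2 against 2), with 4.11 ± 1.95 CPM in male and 60.4 ± 12.4 CPM in female liver. On the male side, an intronic site of Ttc39c fell from 63.2 ± 1.39 CPM in male to 2.37 ± 1.32 CPM in female liver, 25.6-fold (log2 −4.68 ± 0.31). A site in Scara5, which encodes a ferritin receptor, was 24.6-fold lower in female liver (−4.62 ± 0.31), and a site beside the Rh blood group gene Rhd 10.6-fold lower (−3.40 ± 0.26). In all, 286 sites were higher and 786 lower in female than in male liver (edgeR, adjusted p under 0.05), at 186 and 459 nearest genes.

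Among the leading sites higher in female liver, that in 6720401G13Rik (X:47952977–47953914) had the largest difference, with 0.826 ± 0.00874 CPM in male and 46.6 ± 0.343 CPM in female liver (log2 5.77 ± 0.31, edgeR adjusted p = 8.26e-05). The Cux2 site (5:122450279–122451220) had an adjusted p of 0.000521. Sites beside the cytochrome P450 gene Cyp2c39 (19:39580609–39581229, 3.20 ± 0.28) and beside A1bg, which encodes a plasma glycoprotein (15:60746783–60748406, 3.35 ± 0.30), both had an adjusted p of 0.000671. A pair of sites nearest to the sulfotransferase gene Sult2a6 (7:14892565–14893646 and 7:14787654–14788279) were higher by 2.30 ± 0.21 and 3.79 ± 0.34. The organic anion transporter gene Slc22a29 had an intronic site at 15.0 CPM in male and 80.1 CPM in female liver (19:8326367–8327744, 2.41 ± 0.23). Acot4, an acyl-CoA thioesterase gene, had one in its untranslated region (12:85385017–85385333, 3.56 ± 0.34). The list was completed by 4933407K13Rik on X (X:72979928–72980835, 4.04 ± 0.38) and a site beside Gm10414 (6:127291360–127292113, 2.61 ± 0.26, adjusted p = 0.00124). Reads of the near-identical Cyp2c, Cyp3a, Mup and Sult2a family members may be shared, so the member named is uncertain.

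Sites lower in female liver were led by Ttc39c (18:12713656–12714443) and Scara5 (14:66338006–66339839), each with an adjusted p of 0.000186, then Rhd (4:134452711–134453692, 0.000376). A site with no start within 100 kb, in an intron on chromosome 14 (14:11582761–11583801), was lower by −5.22 ± 0.42, with 32.8 CPM in male and 0.844 CPM in female liver. Beside Ndufv1, a subunit of respiratory complex I, the change was −3.74 ± 0.32 (19:4024239–4024978). Cmah, which makes N-glycolylneuraminic acid from its acetyl form, had an intronic site at −2.44 ± 0.22 (13:24456961–24457766). Next came Nos1ap (1:172537293–172538475, −2.61 ± 0.23), the NF-kB inhibitor gene Tnfaip3 (10:18806421–18807251, −4.52 ± 0.42) and the sterol carrier gene Scp2 (4:107803046–107803826, −3.77 ± 0.36). A further intergenic site far from any start lay at 10:47373166–47374535 (−3.22 ± 0.28).

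Differences clustered along the chromosomes. The 1 Mb window from 18:12000001 held 36 sites lower in female liver among 106 tested, 33 of them nearest to Ttc39c, and 2 higher. The window from 4:107000001 held 15 of 68, all nearest to Scp2, and that from 11:16000001 held 9 of 50, of which 7 at Egfr, the epidermal growth factor receptor gene. All 6 tested sites of Scara5 were lower in female liver (median −3.95), as were 5 of 8 at Cyp2d9 and 7 of 10 at Amn1. On the female side, 20 of 23 sites in the window from X:47000001 were higher, all nearest to 6720401G13Rik, and 9 of 42 in the Cyp3a cluster from 5:146000001. The window from 5:122000001 held 8 higher sites among 104, all at Cux2, and 1 lower.

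**Figure D2:**
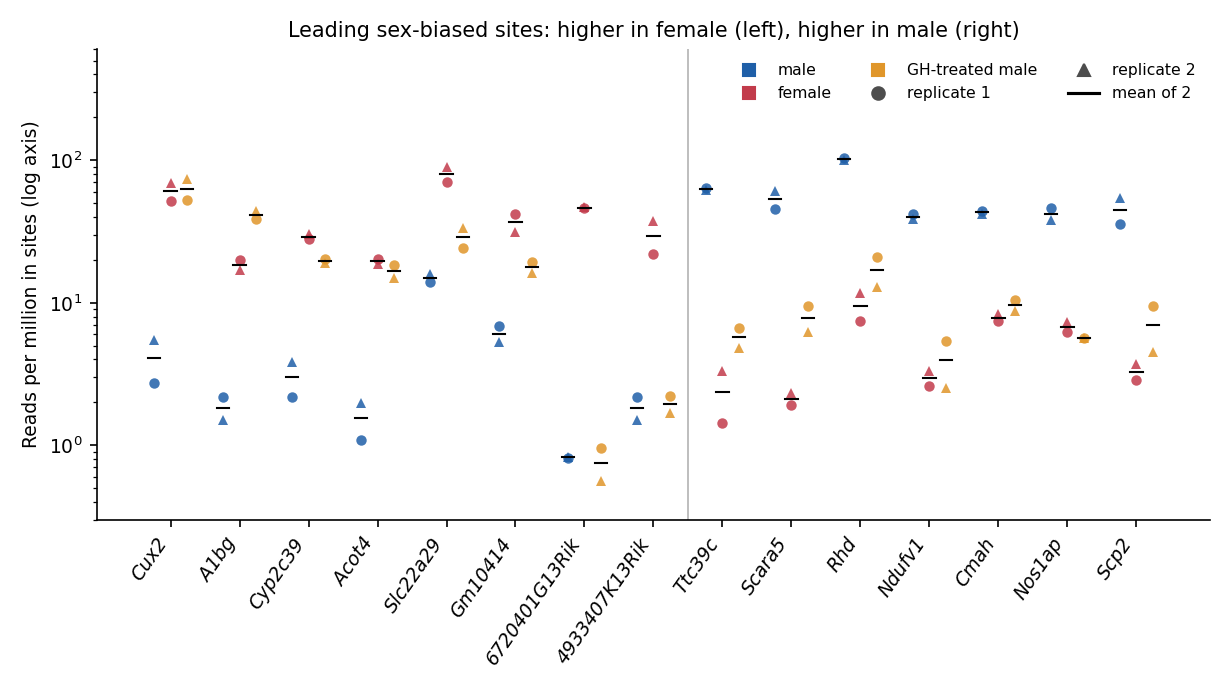
CPM of the leading sites in each library on a log axis, for 15 genes named by the fixed rule (circles, replicate 1; triangles, replicate 2; bars, mean of 2). The Cux2 site is at 4.11 CPM in male, 60.4 in female and 62.8 in GH-treated liver on average, and that of Ttc39c at 63.2, 2.37 and 5.73.

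Genes of the male-biased and female-biased liver lists, fixed before the data were examined, mostly had sites on the side of their name. Of 32 male-biased genes with tested sites, 17 were lower in female liver at 1 or more sites, none higher and 15 passed at no site (2 higher and 20 lower when adjusted over the list alone; camera adjusted p = 1.56e-35, and adjusted p = 0.0802 with an estimated correlation). Examples were the complement gene C6 (−3.89 ± 0.38), the steroid hydroxylase gene Cyp2d9 (−3.03 ± 0.33), the oxysterol hydroxylase gene Cyp7b1 (−3.33 ± 0.39), Nudt7, a peroxisomal diphosphatase gene (−2.74 ± 0.33), the promoter of Mup7, a major urinary protein gene (−2.73 ± 0.35), and the calpain gene Capn8 (−2.95 ± 0.41). Of 36 female-biased genes, 21 were higher, 2 lower (Ntrk2 and Trim24), 1 both (Cux2) and 12 passed at no site (24, 1 and 2 when adjusted over the list alone; camera adjusted p = 3.15e-44, and adjusted p = 0.0608 with an estimated correlation). The examples after Cux2 and A1bg were Cyp3a41b (2.64 ± 0.29), Sult2a1 (2.02 ± 0.23) and Cyp3a16 (2.78 ± 0.38).

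In GH and STAT5 signalling, 4 of 18 genes were lower in female liver, 1 was both higher and lower (Cux2) and 13 passed at no site (7 lower and 1 both when adjusted over the list alone; camera adjusted p = 0.253). Lower were the GH receptor gene Ghr (−2.50 ± 0.36), the repressor gene Bcl6 (−2.01 ± 0.35), Onecut1, which encodes HNF6 (−2.39 ± 0.43), and the cytokine signalling inhibitor gene Socs1 (−1.67 ± 0.36). Socs3 stood at −1.09 ± 0.25 (adjusted p = 0.0534), short of the threshold. Acute phase and inflammation had 3 of 21 genes lower, Hp, Il1r1 and Orm1 (−1.38, −3.12 and −1.35; 1 higher and 7 lower when adjusted over the list alone; camera adjusted p = 2.17e-05, and adjusted p = 0.0608 with an estimated correlation). The cholangiocyte list of 3 genes had 1 lower, Spp1 (−4.27 ± 0.60; 2 when adjusted over the list alone; camera adjusted p = 1.49e-05, adjusted p = 0.0802 with an estimated correlation). Xenobiotic metabolism had 1 of 14 higher, the phenobarbital-inducible P450 gene Cyp2b10 (1.54 ± 0.25; 3 higher and 1 lower when adjusted over the list alone; camera adjusted p = 1.49e-05, adjusted p = 0.123 with an estimated correlation). X inactivation had 3 of 6 higher, Xist, Ddx3x and Eif2s3x (2.88, 0.87 and 1.01; 5 when adjusted over the list alone; camera adjusted p = 5.35e-05, adjusted p = 0.0802 with an estimated correlation).

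The other lists were not called by camera, although housekeeping genes were with the batch as a block (adjusted p = 0.0247, and adjusted p = 0.382 with an estimated correlation, without the block). Lower sites were found at 5 of 23 hepatocyte genes, among them Apob and Hpx (−2.13 and −2.02; camera adjusted p = 0.323), 2 of 22 liver transcription factors (Onecut1 and Trim24; 0.383), 2 of 22 lipid and sterol genes (Elovl6 and Fabp1, −1.59 and −1.58; 0.253) and 1 of 16 clock genes (Bhlhe41, −1.96; 0.383). In the same direction passed 2 of 12 sinusoidal endothelial genes (Bmp2 and Stab2, −3.55 and −1.24; 0.502), 1 of 3 lymphocyte genes (Cd4, −2.12; 0.455) and 1 of 13 housekeeping genes (Eef1a1, −1.62; 0.0538). Eef1a1 lies in the stretch of chromosome 9 where part of the female 2 reads is missing. No gene passed among 4 Kupffer cell (0.414), 8 stellate cell (0.354), 5 erythroid (0.383) and 7 liver-silent genes (0.182).

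The sites higher in female liver had a median log2 of 1.90 (3.73-fold, quartiles 1.35 to 2.63), and 34 of the 286 were on X. Those lower had a median of −2.26 (4.78-fold, quartiles −2.97 to −1.69), and 4 of the 786 were on X. Promoters were 15.0% of the higher and 6.62% of the lower sites, against 27.6% of tested sites (Fisher's exact odds ratios 0.463 and 0.183, p = 5.49e-07 and 5.22e-51). At every called site both libraries of one sex lay beyond both of the other, an arrangement also found at 19.1% (female higher) and 20.9% (male higher) of all tested sites. Within the first processing batch the medians at these sites were 1.80 and −2.12, and within the second 1.66 and −1.96, with all sites in the same direction in both. The count rests on how the variation is modelled: with the batch as a block 1784 sites were higher and 3251 lower, and the second batch alone gave 1116 and 2352. Without male 1 the counts were 561 and 1531, and on leaving out another library they lay between 194 and 288 for higher and between 584 and 699 for lower sites.

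After continuous GH in males, female-type sites were higher and male-type ones lower than in untreated males. The GH-treated libraries also differ in labelled fragment size variation and in file blocks, which cannot be told apart from the treatment. The A1bg site rose 23-fold over male liver (log2 4.52 ± 0.29, n = 2 against 2), from 1.84 ± 0.486 to 41.5 ± 3.98 CPM, with 18.4 ± 2.07 CPM in female liver. The Cux2 site rose 14.4-fold (3.85 ± 0.32) to 62.8 ± 14.9 CPM, beside 60.4 CPM in female liver. The Ttc39c site fell 11.1-fold (−3.47 ± 0.29) to 5.73 ± 1.31 CPM, and that beside Ndufv1 fell 10.2-fold (−3.35 ± 0.32) to 3.96 ± 2.01 CPM. In all, 75 sites rose and 215 fell (edgeR, adjusted p under 0.05), at 56 and 155 nearest genes.

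Leading sites that rose were, after A1bg (adjusted p = 0.000447) and Cux2 (0.00167), those beside 1700055N04Rik (19:3958539–3959357, 3.37 ± 0.28, 0.00167), Acot4 (3.33 ± 0.34, 0.00513), Cyp2c39 (2.63 ± 0.29, 0.00992) and Sult2a6 (7:14787654–14788279, 3.00 ± 0.36, 0.0127). An intronic site at 5:72792393–72793321, far from any start, rose by 1.76 ± 0.21. Sites beside Gm10764 (3.60 ± 0.44), the P450 gene Cyp2a4 (7:27088439–27089135, 2.30 ± 0.31) and the serpin gene Serpina1f (1.84 ± 0.25) followed. The windows of 1 Mb with the most risen sites held Cux2 (5 sites, with 1 that fell), the Cyp2a and Cyp2b cluster from 7:27000001 (4, of which 2 nearest to Cyp2a4) and A1bg from 15:60000001 (3, of which 2 nearest to A1bg).

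Of the leading sites that fell, Nos1ap (−2.87 ± 0.25, adjusted p = 0.00224), Scara5 (−2.77 ± 0.27, 0.00468), Rhd (−2.60 ± 0.26, 0.00468), Cmah (−2.16 ± 0.22, 0.00513) and the intronic site on chromosome 14 (14:11582761–11583801, −3.59 ± 0.37, 0.00513) were also leading in the comparison of the sexes. C330002G04Rik had an intronic site at −2.66 ± 0.30 (adjusted p = 0.0103), and an intergenic site at 8:101478849–101479552 fell by 2.58 ± 0.26 on the log2 scale. The promoter of 2810007J24Rik went from 12 CPM in male to 0.441 CPM in GH-treated liver, with 0.552 CPM in female liver, too few reads for a fold. Most fallen sites per 1 Mb window were at Ttc39c and its neighbours (5 from 18:12000001), Scara5 (3 of 4 from 14:66000001) and Ghr (3 of 4 from 15:3000001).

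**Figure D3:**
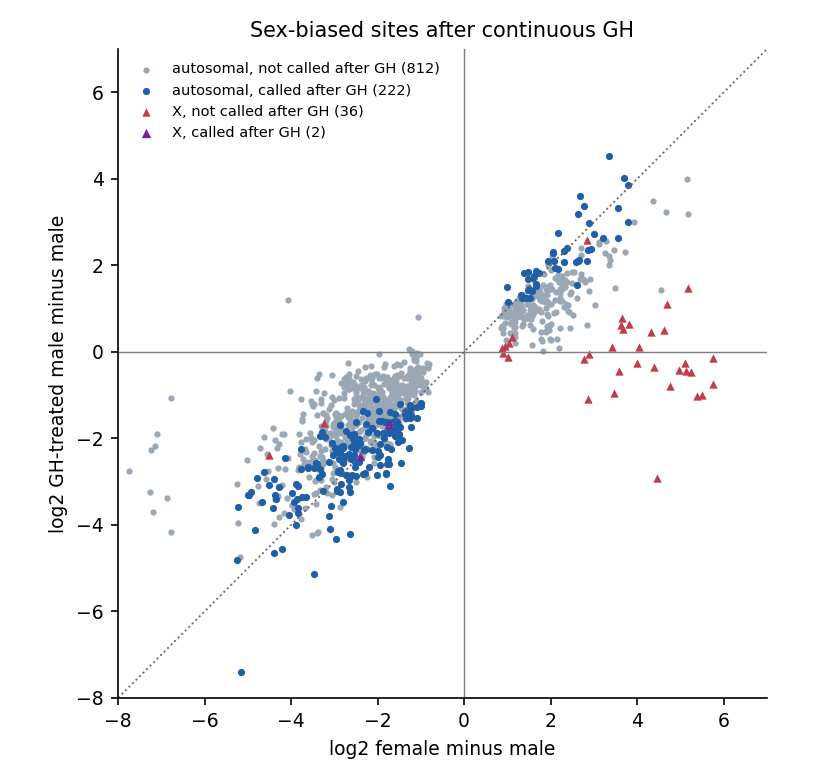
Log2 change after GH against the log2 difference of female from male liver at the 786 sites higher in male and the 286 higher in female liver. The dotted line marks equal change; after GH, 175 of the 782 autosomal male-biased and 47 of the 252 autosomal female-biased sites were called, 2 of the 4 male-biased sites on X, and none of the 34 female-biased ones.

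By list, 5 of 32 male-biased genes fell at 1 or more sites, none rose and 27 passed at no site (20 fell when adjusted over the list alone; camera adjusted p = 4.43e-24, and adjusted p = 0.203 with an estimated correlation). They were C6 (−3.05 ± 0.37), Cyp2d9 (−2.38 ± 0.32), Capn8 (−1.61 ± 0.25), Cyp7b1 (−1.94 ± 0.35) and Mup7 (−2.84 ± 0.52). Elovl3, an elongase of long-chain fatty acids, stood at −2.54 ± 0.50 (adjusted p = 0.0550). Of 36 female-biased genes, 5 rose (among them A1bg, Cyp2a4, Cyp3a41b at 2.09 ± 0.30 and Cyp3a44 at 1.31 ± 0.21), 1 went both ways (Cux2) and 30 passed at no site (19 rose, 2 fell and 1 both when adjusted over the list alone; camera adjusted p = 5.45e-22, and adjusted p = 0.141 with an estimated correlation). In GH and STAT5 signalling Ghr fell (−2.86 ± 0.39), Cux2 went both ways and 16 of 18 passed at no site (1 rose, 4 fell and 1 both when adjusted over the list alone; camera adjusted p = 0.306). Beside the threshold were the promoter of Socs2, an inhibitor of GH signalling, at 12.8 CPM in male, 17.0 in female and 33.0 in GH-treated liver (1.33 ± 0.29, adjusted p = 0.0812), and Socs3 (−1.31 ± 0.26, 0.0565), Bcl6 (−0.98 ± 0.20, 0.0607) and Onecut1 (−2.15 ± 0.45, 0.0667).

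In acute phase and inflammation, the C-reactive protein gene Crp rose (2.08 ± 0.35) and the interleukin-1 receptor gene Il1r1 fell (−2.55 ± 0.43), and 10 genes fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.000417, and adjusted p = 0.141 with an estimated correlation). Camera also called xenobiotic metabolism, where Cyp3a11 rose (2.11 ± 0.37; 0.0297, and adjusted p = 0.319 with an estimated correlation), the clock, where Nr1d1 rose (1.38 ± 0.26; 0.00958, and adjusted p = 0.317 with an estimated correlation), cholangiocytes, where Spp1 fell (−3.13 ± 0.56; 0.00958, and adjusted p = 0.238 with an estimated correlation), and liver-silent genes, of which none passed (0.0328, and adjusted p = 0.278 with an estimated correlation). Of the liver transcription factors, Foxa1 fell (−1.61; camera adjusted p of the list 0.619). Among hepatocyte genes the albumin gene Alb rose (1.53) and Fgg fell (−1.63; 0.525). Elovl6 fell among lipid and sterol genes (−1.60; 0.563), and Pecam1 among sinusoidal endothelial genes (−1.79; 0.116). Kupffer cell (0.858), stellate cell (0.292), lymphocyte (0.0849), erythroid (0.0828), housekeeping (0.842) and X inactivation (0.946) lists had no gene past the threshold. With the batch as a block camera also called GH and STAT5 signalling and sinusoidal endothelium (adjusted p = 0.00946 each, and adjusted p = 0.687 each with an estimated correlation, without the block), and no longer liver-silent genes (0.0919).

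The median change was 1.76 (3.39-fold) at risen and −2.30 (4.92-fold) at fallen sites, and within the second batch, the only one with GH-treated libraries, 1.59 and −2.06. Libraries of the 2 groups did not overlap at any of the called sites, nor at 22.1% (higher) and 23.1% (lower) of all tested sites. Both GH-treated libraries were needed for most calls: without GH 1 the fit called 5 risen and 9 fallen sites, and without GH 2 it called 3 and 0 (edgeR), although all 75 and 215 sites kept their direction in either. At an unadjusted p under 0.05 the full fit had 2767 sites higher and 4497 lower. Without another library the counts rose to between 181 (without male 1) and 323 (without female 1) for risen sites, by way of 216 (without female 2) and 252 (without male 2), and to 611 (without male 2), 671 (without female 2), 755 (without male 1) and 935 (without female 1) for fallen sites. With the batch as a block 1132 rose and 2407 fell, and in the second batch alone 1208 and 2913. The share of risen sites depended on scaling: it was 25.9% of the calls with TMM and 7.93% (57 of the sites risen, 662 fallen) with scaling by autosomal reads, which shifts the median of all sites by −0.17 in this comparison, 0.12 in female minus male and −0.29 in GH-treated minus female.

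Autosomal sex-biased sites as a whole moved toward the female level after GH. Autosomal sites higher in male liver had median levels of 13.4 and 13.5 CPM in the male, 2.39 and 2.91 in the female and 5.07 and 3.67 in the GH-treated libraries. Autosomal sites higher in female liver had 4.37 and 4.49 CPM in the male, 19 and 17.1 in the female and 11.4 and 13.3 in the GH-treated libraries. Of the 786 sites higher in male liver, 177 (22.5%, exact interval 19.6 to 25.6) fell after GH and 782 had a negative change, with a median of −1.58 against −2.26 between the sexes. Of the 252 autosomal sites higher in female liver, 47 (18.7%, exact interval 14.0 to 24.0) rose and all 252 had a positive change, with a median of 1.21 against 1.81. The male-biased count above and the shares under other settings include X. On that basis 47 of 286 female-biased sites (16.4%, exact interval 12.3 to 21.2) rose. A positive change was then seen at 267, with a median of 1.11 against 1.90. Conversely, 177 of the 215 fallen sites were among those higher in male, and 47 of the 75 risen among those higher in female liver, with none in the opposite direction.

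Both contrasts share the male libraries, so part of the excess may come from the shared controls. For independent sets of the same sizes, 3.02 fallen and 0.384 risen sites would be shared. Simulated groups without any difference gave a covariance of the contrasts of 0.0995, against 0.273 observed (correlation 0.476 and 0.557 across sites). Simulated data with the sex effects but GH-treated liver like male gave medians of −0.04 at male-biased and 0.10 at female-biased sites, with 0.110% and 0.628% called. There the sites called between the sexes kept their observed male mean as the true level of both male and GH-treated liver. Noise in the male libraries that helped to select these sites thus counted as signal. Small changes after GH were therefore largely fixed in advance, and they cannot size the effect of the shared controls. The few sites called by chance between the sexes in simulated groups without any difference were 32 male-biased and 35 female-biased in 10 simulations. They had median GH changes of −1.17 and 1.39, in the direction of the sex difference at 90.6% and 85.7% of them. Of them 15.6% and 20% were called after GH, not far from the observed values. All simulations drew the libraries independently and without batches, while replicate deviations in the data correlated at 0.487 between male and female. They therefore cannot show what part of the observed covariance the batches give. With male 1 for the sex contrast and male 2 for GH the covariance was 0.210. The male-biased sites then had a median change after GH of −1.49. With the male libraries exchanged these values were 0.00405 and −0.92. The 2 fits are not alike in batch, as both GH-treated libraries are of the second one. GH-treated liver is compared within that batch when male 2 is used, and across batches when male 1 is used. In the exchanged fit a batch difference enters both contrasts with opposite sign, which lowers their covariance. How much of the drop it gives was not tested. With the batch as a block the covariance was 0.280, and 1553 of 3251 male-biased (47.8%) and 501 of 1784 female-biased sites (28.1%) were called. No simulated groups were fitted with this block, so these shares have no simulated value beside them. Without GH 2, 0% of male-biased and 1.55% of female-biased sites passed, without GH 1 only 1.50% and 2.45%, without female 1 57.5% and 43.0%, without female 2 50.6% and 27.4%, without male 1 38.5% and 19.8%, and without male 2 48.6% and 36.1%.

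Sites called between GH-treated male and female liver in the fit without a batch block were few and mainly on X, and with the block 333 were higher and 285 lower in GH-treated liver. An intergenic site nearest to the P450 gene Cyp2w1 (5:139834402–139835545) was 3.63-fold higher in GH-treated liver (log2 1.86 ± 0.22, n = 2 against 2, edgeR adjusted p = 0.0166), with 70.5 ± 19 CPM in male, 34 ± 0.808 in female and 124 ± 14.4 in GH-treated liver. A site at 13:104381215–104383230, far from any start, was 4.15-fold higher (2.05 ± 0.26, 0.0275), with 91.5, 14.2 and 59.6 CPM. All 16 sites lower in GH-treated liver were X-linked: 14 at 6720401G13Rik (leading site −5.91 ± 0.34, adjusted p = 0.000149), 1 at 4933407K13Rik (−3.92 ± 0.40, 0.0047) and the promoter of Xist, the RNA that silences an X chromosome (X:100676683–100677788, −2.94 ± 0.39, 0.0391; 1.87 CPM in male, 14.0 in female and 1.81 in GH-treated liver).

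No autosomal gene of the male-biased, female-biased or GH signalling lists passed here. Nudt7 stood at 1.97 ± 0.35 (adjusted p = 0.154), A1bg at 1.18 ± 0.22 (0.178), Sult2a1 at −1.38 ± 0.22 (0.113) and the second site of Cux2 at −0.92 ± 0.25 (0.444). Camera called 8 lists, none of which held with an estimated correlation. Lower in GH-treated liver were female-biased genes (adjusted p = 5.31e-07, and adjusted p = 0.410 with an estimated correlation), X inactivation with Xist (1.90e-06, and adjusted p = 0.194) and xenobiotic metabolism (0.0288, and adjusted p = 0.465). Higher were male-biased genes (0.0156, and adjusted p = 0.525), hepatocyte genes (0.0288, and adjusted p = 0.477), lipid and sterol genes (0.0288, and adjusted p = 0.410), clock genes (0.0460, and adjusted p = 0.477) and housekeeping genes (0.0355, and adjusted p = 0.465). The sites of male-biased genes were split in direction, with a median log2 of 0.20 and a mean of −0.20. Adjusted over that list alone, 1 of its genes was higher and 1 lower. With the batch as a block camera no longer called xenobiotic metabolism (0.0779) or the clock (0.189), and did call sinusoidal endothelium (0.0163, and adjusted p = 0.597 with an estimated correlation, without the block). Not called were GH and STAT5 signalling (0.832), liver transcription factors (0.0830), acute phase (0.517), Kupffer cells (0.517), endothelium (0.245), stellate cells (0.832), cholangiocytes (0.0830), lymphocytes (0.219), erythroid cells (0.287) and liver-silent genes (0.497).

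At an unadjusted p under 0.05, 2293 sites were higher and 2255 lower in GH-treated than in female liver. Of the sites higher with the batch as a block, 44 lay where female 2 reads are missing. The second batch alone gave 715 and 595, with 174 of the higher sites in those stretches and 61 others that were high in the male liver libraries of the second batch alone. Without a library the counts of higher and lower sites were 121 and 82 (male 1), 69 and 36 (male 2), 54 and 27 (female 1), 8 and 27 (female 2), 0 and 10 (GH 1) and 1 and 8 (GH 2). Scaling by autosomal reads gave 18 and 33, so that 35.3% of calls were higher against 11.1% with TMM.

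On the X chromosome the female excess was concentrated at 2 loci that bear repeats with roles in X chromosome folding, Firre (6720401G13Rik) and the region of Dxz4 (4933407K13Rik). At 6720401G13Rik 20 of 22 tested sites were higher in female liver, all 20 between X:47903005 and 47976678. Their summed levels were 24.9 ± 2.69 CPM in male, 486 ± 23.1 CPM in female and 26.5 ± 1.12 CPM in GH-treated liver (n = 2 each). At 4933407K13Rik 6 of 9 sites were higher, with 5.45 ± 4.65, 110 ± 1.94 and 4.56 ± 2.06 CPM. The other 8 X sites higher in female liver included those at B230206F22Rik (2 sites, median 0.99), 4930578C19Rik (2.84), Ddx3x (0.87), Eif2s3x (1.01), Tmem29 (1.03) and Xist (2.88). None of the 34 (exact upper limit 10.3%) changed after GH by edgeR, where 2 had an unadjusted p under 0.05, nor did any of the 27 that DESeq2 tested. The lowest adjusted p was 0.0726, at 4930578C19Rik, whose log2 after GH was 2.59, near its 2.84 between the sexes. The median change of the 34 after GH was −0.08, against 3.91 between the sexes, and 16 of them were lower in GH-treated than in female liver (33 at an unadjusted p under 0.05, 18 by DESeq2). Over the 873 tested X sites outside these 2 loci the median log2 was 0.08 above that of the autosomes. All X reads in female liver libraries were 1.45 and 1.49 times those in male ones (replicates 1 and 2), and in naked DNA 1.91 (digested) and 1.77 (sonicated) times.

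**Figure D4:**
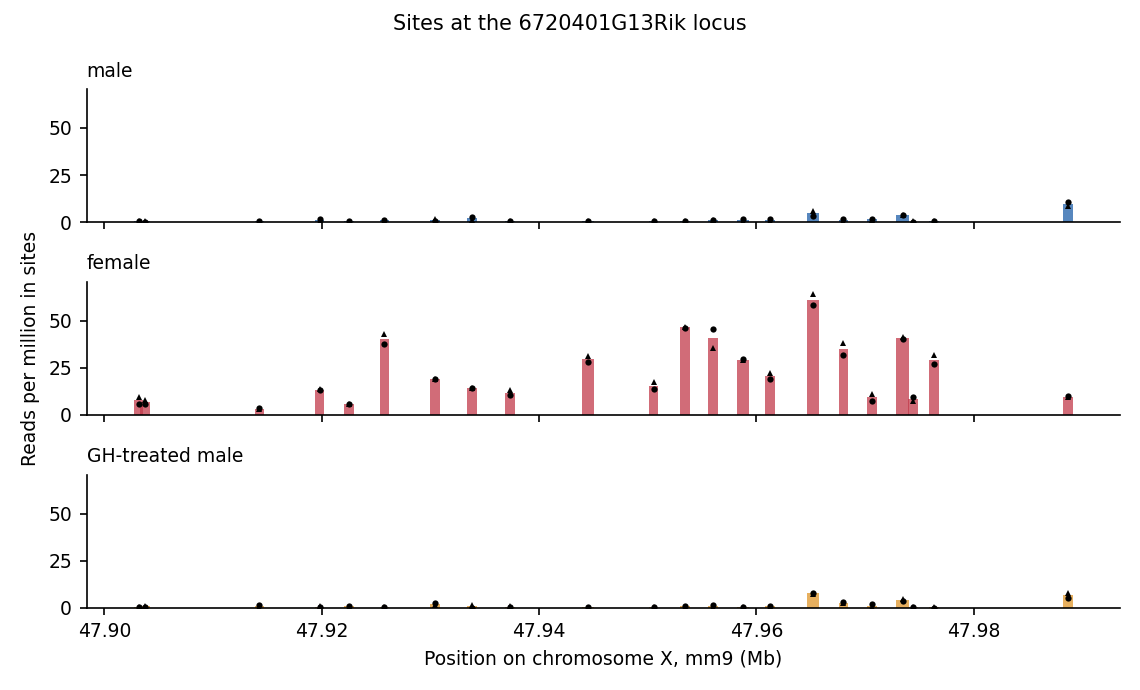
CPM at the 22 tested sites of 6720401G13Rik on X in male, female and GH-treated liver (bars, mean of 2; circles, replicate 1; triangles, replicate 2). The highest site, X:47964625–47965776, has 58.3 and 64.3 CPM in the female libraries.

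The authors' deposited direct lists, chosen on these samples and so not independent evidence, mostly went the same way in the edgeR fit. Of 6047 tested regions listed as higher in male than female liver 92.9% had that direction and 883 (14.6%) passed the threshold, and of 6348 listed as higher in female 98.3% and 344 (5.42%) did. For male over GH-treated liver it was 92.2% of 11388 regions with 180 called (1.58%), and for GH-treated over male 99.5% of 2439 with 79 called (3.24%). None was called in the opposite direction in this fit. With the batch as a block 58.8%, 38.2%, 24.6% and 37.4% of the regions passed, and 4 listed as higher in female and 10 listed as higher in male than GH-treated liver were called in the opposite direction. A listed p-value of exactly 0 was given to 1327, 2378, 1631 and 1373 regions, whose median deposited fold was 1.06, 1.09, 1.09 and 1.1. Whether that fold is scaled by library size is not settled.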

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

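Of the tests given here, the comparisons with the ratio of X copies, the reads of naked DNA at X sites and the reads per site in naked DNA of the second pattern were chosen after the result was seen. The others were written before.

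Mitochondrial reads, which enter no comparison, were above all 4 naked DNA controls in 2 libraries: they made up 0.535% of the reads of male 1 and 0.494% of those of female 1, against at most 0.473% in a control.

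The 34 X sites higher in female liver form the first pattern. At 6720401G13Rik and 4933407K13Rik the median log2 difference was 4.43 (quartiles 3.66 to 5.13, 26 sites), beyond what the ratio of X copies gives, and reads of naked DNA at the 34 sites differed by only 1.16 (interval 0.80 to 1.53; 206 female and 95 male reads), which argues against mapping of repeats as the source. Xist and 4930578C19Rik also lie beyond that ratio (lower difference 2.84, lowest 95% bound 1.82), and at the remaining 6 X sites the median of 0.97 (quartiles 0.90 to 1.03) leaves copies open, as no called X site higher in female liver was below 0.87. A CTCF consensus match was present at 8.82% of the 34 sites and at 8.39% of the other tested X sites (Fisher's exact p = 0.759, odds ratio interval 0.202 to 3.52), so binding of CTCF stays open. A difference between the active and the inactive X, present in females alone, is an untested hypothesis for the sites other than 4930578C19Rik, which in GH-treated males, without an inactive X, stood 2.59 over male liver (adjusted p = 0.0726).

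The second pattern is a set of 61 sites (29 on X, 32 autosomal) high in the male liver libraries of the second processing batch alone, such as those at Vmn2r121 and Brd3, with a median RPM, reads scaled by autosomal reads alone, of 0.158 in male 1, 1.70 in male 2, 0.159 and 0.154 in the female libraries and 2.45 and 1.66 in the GH-treated ones. The set was selected on calls with a log2 over 2 in the second batch alone, both of male 2 over female 2 (median log2 2.44) and of GH-treated over female liver. It was further limited to sites with a log2 of male over female under 1 in the first batch. The levels in the liver libraries, and the calls of all 61 sites in GH-treated over female liver, therefore follow from the selection. Chromatin opened in male liver is argued against by DNase-digested naked DNA, which holds no chromatin and had a median log2 of male over female per site of 3.17 (quartiles 1.27 to 3.73; 50 sites with more male reads, 6 with fewer). Summed over the sites that DNA, from the second batch, had the excess in male (log2 4.11, interval 3.84 to 4.39; 2184 against 118 reads), and sonicated DNA, from the first batch, did not (−0.27, interval −0.76 to 0.21), so reads of Y-linked copies placed elsewhere in a batch without Y are a candidate source. A match to the assembled Y was found at 16.4% of these sites and 0.600% of 1000 others (Fisher's exact p = 1.15e-09), but the Y assembly is partial, and sites without a match stay open.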

How the results depend on the processing

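All alternatives fixed before the data were examined were run. Those chosen after seeing the data were the processing batch block, the second batch alone, loess offsets with the batch block, the direct regions without a listed p-value of 0, and the sites where female 2 reads are missing left out. Of 309 alternative values of the main results 136 stayed within 1.5 times a count or within the spread of a value, and 173 moved. For the 92 pairs of a named site and a comparison, 2085 alternatives gave 1876 on the same side of the threshold, 132 that newly passed and 77 that no longer passed, and none changed sign. Of 1564 alternatives for the 68 called pairs all kept the direction and 1487 the call. At X sites higher in male liver the median change after GH was −2.02 (4 sites), 0.15 in the second batch alone (63 sites) and 4.95 with male 2 for sex and male 1 for GH (25 sites, 20 called in the opposite direction). Of the 63 sites, 29 belong to the second pattern above. Its 61 sites had a median RPM of 0.158 in male 1, against 2.45 and 1.66 in the GH-treated libraries. At such sites a rise over male 1 follows from the selection. How many of the 25 sites are among them was not counted. In GH-treated against female liver the balance of higher and lower sites turned from 2 and 16 to 333 and 285 with the batch block. With 2 libraries per group the simulations recovered 15% (trended dispersion) and 10.4% (tagwise) of 2-fold changes, with 5.44% and 21.9% of calls false. Where a library is left out, its group's lone library is assumed to vary like the others. Unless said, the cause was not tested.

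Counts of sites are given in the order higher and lower in female than male, higher and lower after GH than in male, and higher and lower in GH-treated than female liver. With no filter they were 540, 1528, 216, 976, 68 and 45. With the 4 libraries of the 2 groups alone, a fit on fewer samples, they were 105, 331, 156, 526, 73 and 34. The processing batch block gave 1784, 3251, 1132, 2407, 333 and 285, the second batch alone 1116, 2352, 1208, 2913, 715 and 595, and loess offsets with the batch block 2040, 3216, 1257, 2556, 438 and 314. DESeq2 moved lower in female to 516 and higher in GH-treated than female to 25. Autosomal read scaling moved fallen after GH to 662, and the GH-treated and female counts to 18 and 33. In 500 bp windows these were 384, 13 and 26. With a library left out the ranges were 194 to 561, 584 to 1531, 3 to 323, 0 to 935, 0 to 121 and 8 to 82.

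Replicate number as a block gave 748, 1735, 462, 1218, 88 and 113. Pairing by number is not given: replicate deviations correlated at 0.487 between male and female, but at −0.0123 and 0.00254 with GH-treated liver. Under this block 44.8% of male-biased sites fell after GH (median log2 −1.34) and 25.1% of female-biased rose (0.85).

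The share of male-biased sites that fell was 53.3% with autosomal read scaling (median −2.05), 35.2% with DESeq2, 41.4% with no filter, 28.9% with duplicates removed, 32.7% in 500 bp windows (−1.80), 64.7% with 4 libraries (−1.90), 47.8% with the batch block (−1.08), 61.4% in the second batch (−1.18) and 50.2% with loess offsets and the batch block (−0.99). It was 17.3% with male 2 for sex and male 1 for GH (−0.92) and 3.45% of sites from the deposited lists (−0.63). With a library left out it ranged from 0% to 57.5%, and the median from −2.05 to −1.40. The share of female-biased sites that rose was 25.7% with DESeq2, 45.9% with 4 libraries (median 1.49), 28.1% with the batch block (0.65), 39.4% in the second batch (0.84), 26.9% with loess offsets and the batch block (0.75), 12.3% with male 1 for sex and male 2 for GH (0.84), 11.1% with these exchanged (0.70) and 1.1% of sites from the deposited lists (0.28). With a library left out it ranged from 1.55% to 43.0%, and the median from 1.02 to 1.40.

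Reads in sites were 29.9% in female and 25.7% in GH-treated liver in 500 bp windows, and 4.08%, 3.93%, 5.01% and 5.34% in sonicated male, sonicated female, digested male and digested female DNA. With duplicates removed they were 28.5% in GH-treated liver and 3.09%, 2.94% and 3.72% in the first 3 of these controls. Shared peaks, for male replicates, female replicates, male and female, GH-treated and male, and GH-treated and female, were 60.2%, 63.9%, 58.0%, 50.1% and 52.6% at an overlap of 50% of both regions, a stricter definition by construction, and 96.4%, 93.9%, 88.4%, 87.4% and 83.6% for the stricter 50% of peaks.

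For the deposited direct regions, listed as male over female, female over male, male over GH-treated and GH-treated over male, the share in the listed direction was 87.8%, 97.2% and 86.6% for the first 3 in the stricter 50%, 85.1%, 99.7%, 99.1% and 85.6% with autosomal read scaling, 100%, 99.8%, 99.98% and 100% without a listed p-value of 0, and 94.2% and 89.9% for the last 2 with the batch block. The share called was 24.1%, 9.55%, 2.71% and 0.0791% in the stricter 50%, 10.7% for the first and 5.94% for the third with autosomal read scaling, 18.5%, 8.51%, 1.84% and 7.32% without a p-value of 0, and 58.8%, 38.2%, 24.6% and 37.4% with the batch block. The stricter 50% is ranked by the listed p-value, so for GH-treated over male it holds regions with a p of 0 alone. Of the regions with a p of 0 the shares in the listed direction were 67.4%, 95.9%, 45.8% and 99.1%, and a binomial test of their reads gave a p over 0.05 for 62%, 50.5%, 50.1% and 45.6%. Gene lists called by camera were 6, 7 and 8 in the 3 comparisons, and 0, 0 and 0 with an estimated correlation.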

Other observations

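The predictions for the HNF6 and CUX2 motif and for the STAT5 motif were written before their result was seen. The tests of CTCF, FOXA, HNF4 and CEBP in sex-biased sites had no written prediction. The genes named here were chosen after their values were seen.

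Sex differences were spread over several sites at single genes. Cmah had 6 of 20 tested sites lower in female liver, Cyp7b1 6 of 17 and Nudt7 6 of 26. Higher in female liver were 4 of 7 sites at Cyp2a4, all 3 tested sites of the homeobox gene Dlx4 and 3 of 6 of Setbp1. After GH, 3 of 8 tested sites at Cyp2d9 fell.

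Sequence differed between male-biased and other sites. A match to the consensus of HNF6 and CUX2 (ATYGAT) was present in 49.8% of 769 autosomal male-biased sites and in 30.4% of 3834 matched unchanged sites (Fisher's exact odds ratio 2.27, interval 1.93 to 2.66, adjusted p = 2.54e-23 over 12 tests). A match to the STAT5 consensus was present in 27.2% against 11.6% (odds ratio 2.83, interval 2.34 to 3.43, adjusted p = 1.47e-24). These tests take sites as independent, although sites cluster by locus, with 33 of those lower in female liver nearest to Ttc39c and 15 to Scp2. The intervals and p-values therefore overstate the precision. In 252 female-biased sites the odds ratio was 0.737 (interval 0.502 to 1.06) for HNF6 and CUX2, which argues against a higher frequency there, and 0.837 (0.502 to 1.34) for STAT5, which leaves it open. The CTCF consensus was less frequent in male-biased (odds ratio 0.517, adjusted p = 0.00212) and female-biased sites (0.471, adjusted p = 0.0426), while FOXA (0.919), HNF4 (1.16) and CEBP (0.814) in male-biased sites did not pass.

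A hypothesis from these values is that STAT5 and HNF6 or CUX2 may bind at male-biased sites, where their motifs had odds ratios of 2.83 and 2.27. Binding itself was not measured in these libraries, and a motif match does not show which protein is bound.

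Where part of the female 2 reads is missing, the median log2 over 361 tested sites was −0.52 in female minus male and 0.47 in GH-treated minus female liver. With these sites left out, 299 sites were higher and 825 lower in female than in male liver, 89 rose and 263 fell after GH, and 2 were higher and 17 lower in GH-treated than in female liver.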
